A study of Mus musculus with 8 samples.

How the data were processed

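Memory B cells binding the hapten NIP and positive for the fate-mapping reporter Ai3 were sorted from mouse spleen 30 days after immunization, about 200 cells per library. Per the labels' protocols, cDNA was primed with anchored oligo-dT, extended by template switching and amplified by 17 PCR cycles. Such reads carry no molecular identifiers that the labels name, so reads are not independent molecules and counting errors given here cover counting only. The submitters' processing notes name Trim Galore 0.6.6, STAR 2.2.0, featureCounts and the mouse build mm10, with no role or order; the settings of counting and strand, and the normalization, are not given in the sources used here.

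The authors deposited 1 table of normalized read counts over coding sequence, a signal that is never negative, with 22680 gene symbols and 1 column per library. From the values, each column is a set of whole reads multiplied by 1e+06 and divided by a constant of that library. All values (100%) came out as whole reads within a tolerance of 0.1 of a read. The constants were 5106023 to 7388835 and lay below the recovered totals of 6043933 to 7182209 reads in WT and 7445723 to 8480911 in KO, so columns summed to 1147801 to 1245937 and not to 1e+06. What the constant counts is not given in the sources used here. The normalization therefore left a library's total free to differ, and 3 other scalings were tried. A value above 0 in any library was found for 14766 symbols, and 27 symbols had been turned into dates, which was left as it stood. There were 0 columns of other series.

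KO was compared with WT, 4 libraries each, grouped by the titles in the labels. Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3 (trend and robust empirical Bayes, no covariate) over 6988 genes with a mean of at least 10, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(value + 1) scale and understate the change of low genes. The median log2 fold change of all tested genes was 0.011, and -0.026, -0.014 and -0.0081 under TMM, median-of-ratios and quantile scaling. Between replicates the median coefficient of variation per gene was 23.4% in WT and 21.3% in KO, against 6.63% and 5.91% from counting alone, so variation between libraries and not depth set most of the error of genes at these levels.

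The comparison, the test, most of the alternatives, 29 gene lists and the rule for naming genes were fixed before the data were examined. The rule named Zfp318, Ighm and Ighd in every case. It then named the 12 genes with the largest positive and the 12 with the largest negative change among genes past the threshold with a mean of at least 50 and no overlap between groups, leaving out predicted genes and receptor variable segments. If fewer than 5 genes passed in a direction, the 10 with the smallest unadjusted p were to be named as not passing, which was not needed. It also named up to 4 tested members per list with the smallest unadjusted p. Igkc, Iglc1, Iglc2, Iglc3, Igha, Pdcd1lg2 and the genes of the closing section that fall outside this rule were chosen after their values were seen.

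Lists with at least 5 tested members, 26 of the 29, were tested with limma's camera at its preset inter-gene correlation of 0.01, which compares a list with the other tested genes. The counts of members past the threshold are given over all genes tested and adjusted over the list alone. The design fixed in advance did not say whether camera should model a trend of variance with mean. The version with a trend was run first, and its results, other splits of the libraries included, were seen before camera's default without a trend was taken as the reported setting. Both give 11 lists, but they differ in how other splits of the libraries behave and after length correction, and both versions are given in the closing section.

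Coding lengths and transcript GC came from the GENCODE vM21 annotation of GRCm38, where 20140 symbols matched directly and 240 through older symbols, and 2298 did not match. Of the tested genes 6791 (97.2%) had a coding length. The length and GC correction smoothed each library's deviation from the gene means over both with natural splines of 5 degrees of freedom each and removed the fit. It was added after the data were seen, as were the fits without WT replicate 1 or without WT replicate 1 and KO replicate 1 that go with it, the versions of camera with a trend, and an estimated correlation under other settings. List medians were also compared with those of 10000 random lists of tested genes matched on coding length and mean level, in 15 bins of length and 4 of level. Since the length trend runs along the groups, the correction can also remove real differences that follow length.

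The count tests edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 were run as alternatives on the recovered reads and called 180 and 393 genes, of which 100 and 100 were among the 107 of limma. The other alternatives were pseudocounts of 0.5 and 5, no filter and a minimum mean of 50, limma without trend or robust, array weights, the replicate number as a block, an adjusted p below 0.1, camera with an estimated correlation, fry, list members with a mean of at least 50, and leaving out each library in turn. Single values, such as shares of immunoglobulin reads, were compared with exact two-sided permutation tests. Figures were drawn with matplotlib 3.10.9.

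The fits were tested on simulated data for KO against WT, drawn for the 6988 tested genes with 200 changed. limma recovered 22.4% of genes changed by 1.5-fold, 59.7% by 2-fold and 97.0% by 4-fold, with 11 unchanged genes called. edgeR recovered 23.9%, 61.2% and 97.0% with 10 unchanged genes called, and DESeq2 28.4%, 68.7% and 98.5% with 19. In data with no change limma and edgeR called 0 genes and DESeq2 called 2. Changes under 2-fold are therefore often missed with 4 libraries per group. The simulated data were a single draw with independent genes and no library set apart like WT replicate 1. Recovery and false calls in the real data may therefore be worse. In data simulated with a length trend alone, at the slope of 0.127 log2 units per doubling of coding length seen here, camera passed 6 lists and limma called 3 genes before the correction, and 0 and 0 after it.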

Results

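Bulk RNA sequencing profiled mouse memory B cells from the spleen 30 days after immunization with the hapten carrier conjugate NP-KLH, given with lipopolysaccharide and alum. Memory B cells are the antigen-experienced cells that answer a second exposure. The cells bound NIP, a hapten related to NP, carried B220 and CD38 on their surface, and lacked CD138, GL7 and FAS. They also expressed Ai3, a reporter at Rosa26 that is switched on by AID-cre and so marks cells with a history of AID expression. The 8 libraries formed 2 groups, 4 from wild-type mice (WT) and 4 from mice with the Zfp318 allele that the labels write as ZSDAT on both chromosomes (KO). Each library started from about 200 sorted cells, and 5 mice were used for sorting in each experiment. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these libraries, which may be technical. The WT libraries held 6043933 to 7182209 reads over the listed genes and the KO libraries 7445723 to 8480911, so every KO library was deeper than every WT library. They detected 10877 to 12152 genes. Every pair of libraries within a group differed by more than counting noise, with a chi-square per degree of freedom of at least 13.3 in WT and 18.7 in KO.

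The comparison of KO with WT asks which transcripts of these memory B cells depend on ZFP318, a zinc finger protein known for its part in IgD expression; the title of the series names mitochondrial function. Zfp318 itself lies on chromosome 17 at positions 46383731 to 46420920 of GRCm38 (mm10), on the plus strand, as gene ENSMUSG00000015597.17. Its normalized read count fell from 74.4 ± 20.4 in WT to 2.35 ± 0.453 in KO (SD, n = 4 each), a log2 fold change of -4.46 (SE 0.34, limma adjusted p = 8.3e-09). The 4 WT libraries held 101.0, 61.0, 56.2 and 79.5, and the 4 KO libraries 2.98, 2.33, 2.19 and 1.91, so every library matched its label. These values rest on 322 to 582 reads per WT library and 12 to 22 per KO library. An exact two-sided permutation test gave p = 0.0286, the smallest that the 70 arrangements of 4 against 4 allow. The labels do not say which part of the gene the allele alters.

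In KO memory B cells the transcripts of Cxcr3, Apoe and Lgals1 and of the IgD and IgG heavy chains were lower, and those of Ighm, Mlxip, Polr2a and Kmt2d higher. Among the genes lower in KO, Cxcr3, a receptor for interferon-induced chemokines, fell from 87.8 ± 8.26 to 14.3 ± 6.54 (log2 fold change -2.62, SE 0.28, limma adjusted p = 1.4e-06). Apoe, a lipid carrier, fell from 2044 ± 384 to 1030 ± 120, and Lgals1, which encodes galectin-1, from 159 ± 14.1 to 77.9 ± 18.8. Ebpl and Pla2g7, a secreted phospholipase, fell by 0.96 and 0.99 on the log2 scale, and Alyref, an adaptor for mRNA export, and Xbp1, a transcription factor of the unfolded protein response, fell by 0.90 and 0.86. Among the genes higher in KO, Mlxip, a glucose-sensing transcription factor, rose from 42.4 ± 7.16 to 137 ± 30.0 (log2 fold change 1.66, SE 0.20, limma adjusted p = 1.5e-05). Polr2a, the largest subunit of RNA polymerase II, rose from 119 ± 17.7 to 278 ± 38.3, and Kmt2d, a histone methyltransferase, from 75.6 ± 22.6 to 184 ± 79.1. The other 9 genes named by the rule for higher genes were Atxn2l, Irak1, Ifi213, Glcci1, Gcn1l1, Zmiz2, Tcf3, Tmc6 and Brwd1, with log2 fold changes between 0.83 and 1.04. Irak1 is a kinase of Toll-like receptor signaling, Tcf3 a transcription factor of B cell development, and Brwd1 a bromodomain protein.

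In total 107 of 6988 genes tested changed at a limma adjusted p below 0.05, of which 54 were higher and 53 lower in KO, and 21 were immunoglobulin genes. At an unadjusted p below 0.05 there were 1264 genes, and the 4 KO and 4 WT values did not overlap for 691 genes, 9.89% of those tested against 2.86% by chance. The 2.86% is an expectation per gene. Genes share shifts between libraries, so the share in a given split can lie far from it, and other splits were not counted. The number of calls hung on single libraries. Without WT replicate 1, which stood apart from the other WT libraries, 565 genes passed, 345 higher and 220 lower. Under median-of-ratios scaling 624 then passed, 224 higher and 400 lower, so the balance of directions depended on the scaling. Without WT replicates 2, 3 and 4 the counts were 29, 31 and 58, and without KO replicates 1, 2, 3 and 4 they were 40, 62, 39 and 48. In all 8 of these fits 25 genes were called, 8 higher and 17 lower, 14 of them immunoglobulin genes. They included Zfp318, Ighm, Ighd, the 4 IgG genes, Cxcr3, Mlxip, Polr2a, Lgals1, Apoe, Ebpl, Gpx1 and Mrps15. Of these, Ighm, Lgals1, Apoe, Ebpl, Gpx1 and Mrps15 lost the call in 1 other alternative and Ighg3 in 2. Their limma adjusted p there was up to 0.172. Kmt2d lost its call in 4 of 24 alternatives, with a limma adjusted p of up to 0.15. Among these were the fits without WT replicate 2 or 3, at up to 0.0688. Ifi213 and Pla2g7 kept their calls in 4 of the 8 leave-one-out fits. Atxn2l, Irak1, Glcci1, Gcn1l1, Zmiz2, Tcf3, Tmc6, Brwd1, Alyref and Xbp1 kept theirs in 1 to 3 of the 8. Leaving out WT replicate 2 or WT replicate 3 ended the call of each of these 10 genes.

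Fold changes also followed the coding length of genes. Over the 6791 tested genes with an annotated coding length, Spearman's rho between log2 fold change and length was 0.42 across genes, which are not independent replicates. The median log2 fold change ran from -0.22 in the shortest of 10 equal bins of genes to 0.24 in the longest. Genes higher in KO had a median coding length of 2118 bases, genes lower in KO 535.5 bases and all tested genes 1335 bases. Library by library, the deviation from the gene means correlated with length at rho 0.16 to 0.24 in KO and at -0.35 to -0.041 in WT, closest to 0 in WT replicate 1. After a trend over length and GC content was removed from each library, a step chosen after seeing the data, 61 genes passed, 41 higher and 20 lower, and 41 of them were among the 107. The other 66 calls ended, all 66 with the same sign and with 41.7% to 95.9% of the log2 fold change left (median 74.0%). Their median SE was 0.18 before and 0.17 after, so they ended because fold changes shrank and because, with fewer genes passing, the highest unadjusted p of a call dropped from 7.4e-04 to 4.4e-04. Among the genes named above, the log2 fold change went from 1.04 to 0.72 for Atxn2l, 0.93 to 0.68 for Irak1, 0.87 to 0.53 for Gcn1l1 and 0.86 to 0.53 for Zmiz2. It went from 0.85 to 0.56 for Tcf3, 0.84 to 0.55 for Tmc6, 0.83 to 0.65 for Brwd1, -0.90 to -0.70 for Alyref and -0.86 to -0.72 for Xbp1 (SE 0.17 to 0.26 after the step). Kmt2d, whose coding length is 16764 bases, went from 1.23 to 0.93 and kept its call narrowly (limma adjusted p = 0.04995).

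**Figure D1:**
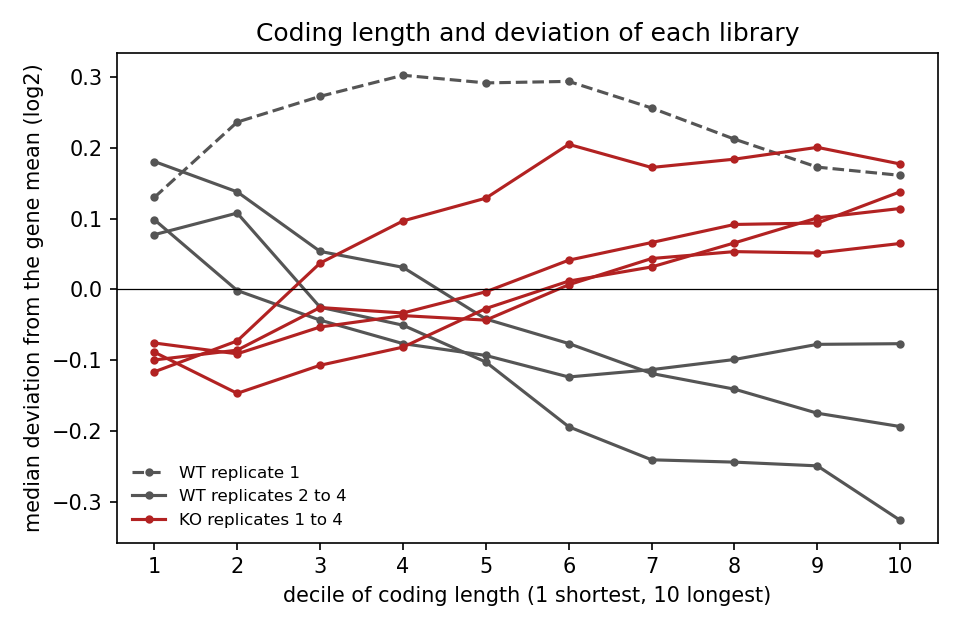
Median deviation of each library from the gene means (y axis, log2) in 10 equal bins of the tested genes ordered by coding length (x axis, 1 shortest to 10 longest), one line per library. The 4 KO lines are below 0 in the shortest bin and above 0 in the longest, WT replicates 2 to 4 the reverse, and WT replicate 1 (dashed) lies above the mean in every bin.

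Immunoglobulin transcripts moved away from IgG, IgD and lambda 1 and toward IgM and kappa. Ighm, the IgM heavy chain, rose from 8765 ± 591 to 12747 ± 404 (log2 fold change 0.54, SE 0.087, limma adjusted p = 7.5e-04). Ighd, which shares a transcription unit with Ighm, fell from 229 ± 57.6 to 69.1 ± 15.8 (log2 fold change -1.71, SE 0.19, adjusted p = 3.3e-06). All 4 IgG genes fell: Ighg2c from 96.7 ± 35.5 to 13.5 ± 4.82, Ighg1 from 155 ± 32.0 to 27.9 ± 10.0, Ighg2b from 399 ± 53.1 to 115 ± 46.4 and Ighg3 from 185 ± 54.0 to 95.4 ± 9.58. The IgG genes took 8.46% ± 0.724 of heavy chain constant reads in WT and 1.93% ± 0.348 in KO (n = 4 each; exact permutation p = 0.0286, adjusted 0.0464 over 13 immunoglobulin measures). The ratio of IgM to IgD reads was 39.5 ± 6.64 in WT and 192 ± 44.1 in KO (exact permutation p = 0.0286, adjusted 0.0464, n = 4 each). Ighm, Ighd and each IgG gene already separated the groups in every library, so these 2 permutation tests were fixed in advance and add nothing to the single genes. Here and in the closing section 0.0286 is the smallest permutation p possible. The 13 measures share genes and several tie at it, so the adjusted 0.0464 depends on how many such measures were included. Among light chain genes Igkc rose (log2 fold change 0.61) and Iglc1 fell (-0.82), while Iglc2 and Iglc3, at -0.13 and 0.30, and Igha, at -1.94, did not pass. Iglc1 lost its call after length and GC correction (log2 fold change -0.58, SE 0.14, against -0.82, SE 0.12; adjusted p = 0.0794). Of the 11 tested constant genes 2 were higher and 6 lower over all genes tested, and 3 were higher and 7 lower adjusted over the list alone. The list was lower in limma's camera test (median log2 fold change -0.91, adjusted p = 1.4e-04), and adjusted p = 0.351 with an estimated correlation. Camera weighs genes alike: summed over the list's genes, counts stood at 26223 ± 2736 in WT and 30619 ± 1040 in KO. Total constant gene reads were thus not lower. The IgG genes resemble each other, as do Iglc1 to Iglc3, so reads could be split between copies and the level of each single gene is uncertain.

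**Figure D2:**
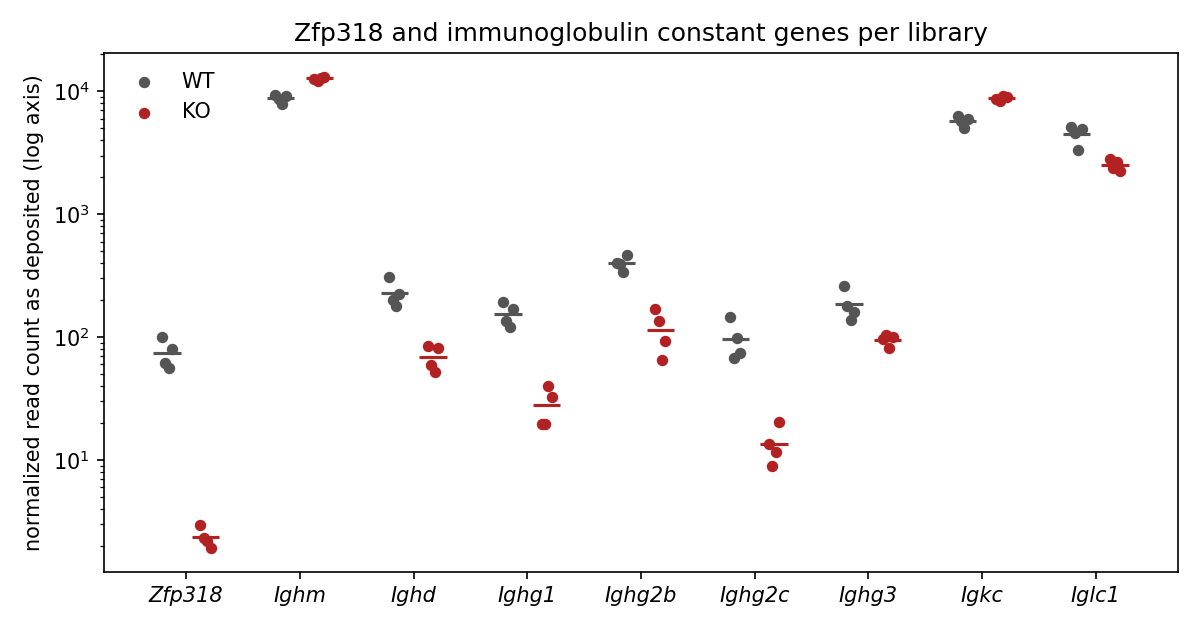
Normalized read count as deposited (y axis, log scale) of Zfp318 and of immunoglobulin constant genes in each of the 4 WT (grey) and 4 KO (red) libraries, with bars at group means. The KO values of Zfp318, Ighd and the IgG genes lie below every WT value, and those of Ighm and Igkc above.

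At camera's preset correlation the lists of nuclear genes of complexes I and IV, ATP synthase and the mitochondrial ribosome were lower in KO and that of mitochondrially encoded genes higher. Only Cox4i1 and Mrps15 of their members passed over all genes tested, and none of these lists passed with an estimated correlation. Member calls hung on WT replicate 1: without it, complex I had 9 lower and 1 higher over all genes tested. Complexes II and III, complex IV, ATP synthase and the mitochondrial ribosome then had 2, 5, 2 and 8 lower and 0 higher. Of 36 tested genes of complex I, the NADH dehydrogenase, 33 had a negative log2 fold change, with a median of -0.26 (camera adjusted p = 8.3e-06, and adjusted p = 0.118 with an estimated correlation). None passed over all genes tested and 6 were lower adjusted over the list alone; Ndufb8, at 162 ± 23.3 in WT and 108 ± 9.08 in KO, had the smallest p (limma adjusted p = 0.0706). At an unadjusted p, Ndufa13, Ndufa2 and Ndufa11 came next, with log2 fold changes of -0.40, -0.38 and -0.38. Complex IV, cytochrome c oxidase, had a median of -0.26 over 15 genes (camera adjusted p = 0.0022, and adjusted p = 0.118 with an estimated correlation). Its subunit Cox4i1 fell from 2104 ± 120 to 1564 ± 33.9 (limma adjusted p = 0.0315), the only member past the threshold over all genes tested, against 5 adjusted over the list alone; Cox8a, Cox5a and Cox6a1 were at -0.39, -0.37 and -0.36. ATP synthase genes had a median of -0.15 over 16 genes (camera adjusted p = 0.0172, and adjusted p = 0.351 with an estimated correlation), with 0 members past the threshold over all genes tested and 1 adjusted over the list alone. Atp5l, Atp5h, Atp5g3 and Usmg5 were at -0.48, -0.28, -0.30 and -0.30. Mitochondrial ribosome genes had a median of -0.17 over 74 genes (camera adjusted p = 1.4e-04, and adjusted p = 0.118 with an estimated correlation). Mrps15 fell from 249 ± 6.84 to 147 ± 14.2 (limma adjusted p = 0.0044) as the only member past the threshold over all genes tested, against 5 adjusted over the list alone; Mrpl43, Mrpl57 and Mrps16 were at -0.52, -0.69 and -0.47. The 13 tested genes of complexes II and III, among them Uqcr10, Uqcrq, Sdhd and Uqcrfs1 at -0.39, -0.38, -0.59 and -0.30, had a median of -0.16. The list did not pass (camera adjusted p = 0.0812, and adjusted p = 0.351 with an estimated correlation), with 0 members past the threshold over all genes tested and 0 adjusted over the list alone. Without WT replicate 1 it passed (camera adjusted p = 0.0491), but not with an estimated correlation.

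All 11 tested mitochondrially encoded genes had a positive log2 fold change, with a median of 0.58 (camera adjusted p = 1.4e-04, and adjusted p = 0.468 with an estimated correlation). The median was 0.38 without WT replicate 3 and 0.73 without WT replicate 1, with the call kept. None passed over all genes tested and 4 were higher adjusted over the list alone. mt-Nd4 stood at 2076 ± 748 in WT and 3374 ± 606 in KO, and mt-Cytb, mt-Nd1 and mt-Co1 were at log2 fold changes of 0.46, 0.58 and 0.46. Summed over the list, the WT libraries held 16935 to 28980 and the KO libraries 26824 to 41711, so the groups overlapped. The genes of the nuclear lists are short, with median coding lengths of 387 to 582 bases, and their medians moved toward 0 once the length and GC trend was removed: -0.07 for complex I (camera adjusted p = 0.0626), -0.05 for complex IV (0.454), 0.0064 for ATP synthase (0.995) and -0.0089 for the mitochondrial ribosome (0.934). The mitochondrially encoded list kept its call, with a median of 0.64 (camera adjusted p = 7.2e-07, and adjusted p = 0.712 with an estimated correlation). Over all genes tested, mt-Cytb and mt-Nd1 then passed (limma adjusted p = 0.0144 and 0.0202), and mt-Co1 and mt-Nd4 did not (0.0751 and 0.0815). Cox4i1 lost its call after this step (log2 fold change -0.32, SE 0.097, against -0.43, SE 0.10; adjusted p = 0.122) and in 7 of 8 leave-one-out fits, all but that without WT replicate 1, with an adjusted p of up to 0.169. The call of the ATP synthase list ended without WT replicate 2 (0.0548), WT replicate 4 (0.0684) or KO replicate 4 (0.0821).

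**Figure D3:**
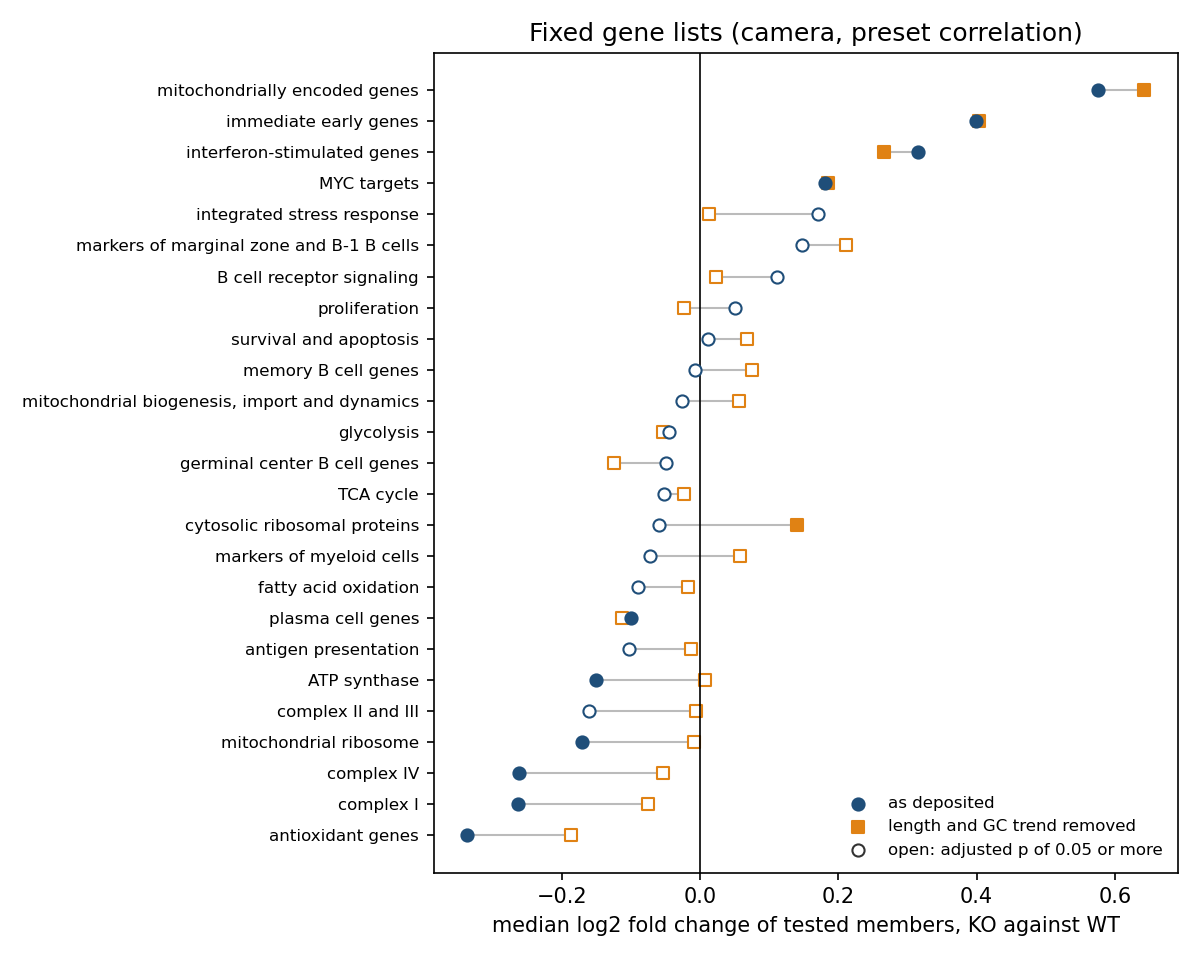
Median log2 fold change of KO against WT (x axis) of 25 gene lists before (circles) and after (squares) removal of each library's trend over coding length and GC content; filled symbols passed limma's camera test at an adjusted p below 0.05. The immunoglobulin constant list, at -0.91 and -0.87, lies off the scale and is not drawn.

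Other metabolic lists held few calls. Antioxidant genes were lower, with a median of -0.34 over 17 genes (camera adjusted p = 0.0016, and adjusted p = 0.357 with an estimated correlation). After length and GC correction the median was -0.19 and the list did not pass (0.0620). Among 10000 random lists matched on coding length and mean level its median lay at percentile 0.71 (random lists -0.15). Gpx1, a glutathione peroxidase, fell from 1748 ± 102 to 1151 ± 84.7 (limma adjusted p = 0.0026). Hmox1, the inducible heme oxygenase, rose from 6.56 ± 3.10 to 27.5 ± 10.5 (adjusted p = 0.0163), a call that ended without WT replicate 3 or KO replicates 2, 3 or 4 (adjusted p of up to 0.0812). Adjusted over the list alone, 1 gene was higher and 4 lower, with Txn1 and Gpx4 at -0.48 and -0.49. No member of the lists for mitochondrial biogenesis, import and dynamics, the TCA cycle, glycolysis, fatty acid oxidation, the integrated stress response or cytosolic ribosomal proteins passed over all genes tested, and none of these lists passed camera (adjusted p = 0.948, 0.937, 0.963, 0.937, 0.948 and 0.402). Adjusted over the list alone, 1 gene was higher and 2 lower in the biogenesis list and 0 in the other 5. In the biogenesis list Tomm22 and Tomm20, receptors of protein import, were at -0.61 and -0.45, and Pprc1 and Tomm40 at 0.76 and 0.60. In the TCA cycle list Suclg1, Dlst, Ogdh and Fh1 were at -0.37, 1.08, 0.58 and -0.30, and in glycolysis Pfkl, Pgam1, Slc2a1 and Gpi1 at 0.55, -0.47, 0.42 and 0.17. Etfa, Acadl, Acadvl and Hadha of fatty acid oxidation were at -0.40, -0.40, 0.37 and 0.34, and Ppp1r15a, Mthfd2, Atf4 and Eif4ebp1 of the stress response at 0.41, -0.90, 0.23 and -0.42. Median and mean differed in sign for biogenesis (-0.027 and 0.0057), the TCA cycle (-0.053 and 0.013) and glycolysis (-0.045 and 0.022), each with a negative camera direction. Their medians turned positive in some leave-one-out fits: biogenesis without WT replicate 1 (0.11), KO replicate 1 (0.010) or KO replicate 4 (0.040), the TCA cycle without WT replicate 1 (0.015), and glycolysis without WT replicate 1 (0.036), KO replicate 1 (0.016) or KO replicate 3 (0.021) and under quantile normalization. Cytosolic ribosomal proteins, with Rpl35, Rpl17, Rpl13 and Rpl37a at -0.32, 0.27, -0.25 and -0.26, had a median of -0.06 that became 0.14 after length and GC correction (camera adjusted p = 1.8e-04), -0.10 without WT replicate 1 (4.9e-05) and 0.11 with both changes, where the call ended (0.306). With an estimated correlation, adjusted p = 0.986 as first fitted, 0.998 after the correction and 0.602 without WT replicate 1. Leaving out WT replicate 1 called 2 ribosomal protein genes higher and 26 lower over all genes tested. That fit also called 2 higher and 2 lower in the biogenesis list, and 1 higher each in the TCA cycle and glycolysis lists. After length and GC correction Rpl17 passed (log2 fold change 0.51, limma adjusted p = 0.0033).

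Genes tied to B cell fates changed in both directions within the same list. Among 30 memory B cell genes, Tcf3, Foxp1 (404 ± 47.2 to 602 ± 34.6) and Foxo1 (144 ± 46.5 to 236 ± 19.1) rose, and Gpr183, a receptor that guides B cell positioning, fell from 198 ± 16.9 to 131 ± 6.46. With Pdcd1lg2, which encodes PD-L2 and fell from 28.3 ± 6.73 to 10.8 ± 2.87, that made 3 higher and 2 lower over all genes tested, and 6 higher and 6 lower adjusted over the list alone. The list did not move one way (median -0.0076, camera adjusted p = 0.962). The median was positive under quantile normalization and in 6 of the 8 leave-one-out fits, all but those without WT replicate 3 or KO replicate 4, at up to 0.10 without WT replicate 1. Among 8 germinal center genes Bcl6, the master repressor of that program, rose from 21.4 ± 9.10 to 51.2 ± 8.27 and Fas, a death receptor whose protein the sort selected against, fell from 35.9 ± 13.1 to 13.2 ± 2.25, the same 1 higher and 1 lower adjusted over the list alone; Myo1c and Cd86 were at 0.62 and -0.40, and the list did not pass (median -0.05, camera adjusted p = 0.948). Its median was 0.14, 0.13 and 0.16 without WT replicate 1, KO replicate 2 and KO replicate 4, so it had no stable sign. The plasma cell list was lower (27 genes, median -0.10, camera adjusted p = 0.0172, and adjusted p = 0.351 with an estimated correlation). Its genes Xbp1, Manf (236 ± 32.4 to 146 ± 11.8) and Herpud1 (228 ± 13.3 to 152 ± 14.4), which serve protein folding and disposal in the endoplasmic reticulum, fell, while Pdia4 was at 0.46 and did not pass. Adjusted over the list alone, 1 gene was higher and 4 lower. The call of this list ended without WT replicate 3 (0.0563) or KO replicate 1 (0.0533), and after length and GC correction, where the median went from -0.10 to -0.11 (0.0626). Its median was -0.18, -0.17 and -0.18 without WT replicates 2, 3 and 4, and -0.17, -0.20 and -0.25 without KO replicates 2, 3 and 4. Of the gene calls named for these lists, each ended in 4 to 7 of the 8 leave-one-out fits, with adjusted p of up to 0.175 and never without WT replicate 1. After length and GC correction none of them passed (adjusted p of 0.0662 to 0.168). Herpud1 went from -0.58 to -0.54 (SE 0.14 both times), Bcl6 from 1.33 to 1.20 (SE 0.31), Foxo1 from 0.76 to 0.65 (SE 0.18 and 0.17), Fas from -1.30 to -1.10 (SE 0.32) and Pdcd1lg2 from -1.32 to -1.14 (SE 0.33). Foxp1 went from 0.58 to 0.42 (SE 0.12), Gpr183 from -0.59 to -0.43 (SE 0.15 and 0.14) and Manf from -0.69 to -0.46 (SE 0.15 and 0.14).

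In B cell receptor signaling (32 genes, median 0.11, camera adjusted p = 0.433) no gene passed over all genes tested, and 2 were higher and 2 lower adjusted over the list alone. Without WT replicate 1 its median was 0.27, 8 members were higher and the list passed (0.0493, and adjusted p = 0.730 with an estimated correlation), while the median was 0.0023 without WT replicate 3 and 0.041 without KO replicate 4. Dok3 and Cr2 were at 0.55 and 0.48, and Cd81 and Fcgr2b at -0.48 and -0.43. Antigen presentation genes (22 genes, median -0.10, mean 0.028, negative camera direction, adjusted p = 0.715) had no call over all genes tested and 3 higher and 5 lower adjusted over the list alone, with the class II genes H2-Eb1, H2-Ab1, H2-Aa and H2-Oa at -0.34, -0.31, -0.29 and -0.35. The list median turned positive without WT replicate 1 (0.067, with 4 members higher and 3 lower) and was -0.0047 without KO replicate 1. Markers of marginal zone and B-1 B cells (14 genes, median 0.15, camera adjusted p = 0.610) had none over all genes tested and 5 higher and 2 lower adjusted over the list alone, with Cr2, Pik3r4, Zbtb32 and Myof at 0.48, 0.47, -0.82 and 0.42. This list passed when tested genes were limited to a mean of at least 50 (median 0.42, camera adjusted p = 0.0110, and adjusted p = 0.471 with an estimated correlation).

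The MYC target, immediate early and interferon lists were higher in KO at camera's preset correlation. MYC targets had a median of 0.18 over 30 genes (camera adjusted p = 0.0172, and adjusted p = 0.821 with an estimated correlation). Myc rose from 254 ± 25.3 to 392 ± 50.0 (limma adjusted p = 0.0190) and Mybbp1a, a nucleolar protein, from 152 ± 27.7 to 241 ± 35.1 (adjusted p = 0.0315), the 2 calls over all genes tested against 3 adjusted over the list alone; Fbl and Cad were at 0.49 and 0.65. Both gene calls held in 2 of the 8 leave-one-out fits, those without WT replicate 1 among them (adjusted p of up to 0.130), and after length and GC correction Myc passed (0.0181) and Mybbp1a did not (0.67 to 0.44, SE 0.16 and 0.15; 0.194). The list call ended without WT replicate 3 (median 0.099, adjusted p = 0.0908) or KO replicate 1 (0.0540), and the median was 0.30 without WT replicate 1. Immediate early genes, which respond within minutes to stimulation, had a median of 0.40 over 19 genes (camera adjusted p = 9.7e-04, and adjusted p = 0.398 with an estimated correlation), with 0 calls over all genes tested and 7 higher adjusted over the list alone; the median was 0.26 without WT replicate 4. Nr4a1, at 16.4 ± 6.79 in WT and 36.1 ± 6.79 in KO, Egr1, Nfkbid and Zfp36 were at 1.16, 1.21, 0.47 and 0.72. Interferon-stimulated genes had a median of 0.31 over 19 genes (camera adjusted p = 0.0296, and adjusted p = 0.468 with an estimated correlation), with 0 calls over all genes tested and 1 higher adjusted over the list alone; Trim30a, Bst2, Oasl1 and Isg20 were at 0.92, 0.47, 0.85 and 0.45. This list call ended without WT replicate 2 (0.101), KO replicate 1 (0.0823) or KO replicate 2 (0.115), and its median was 0.20 without WT replicate 3. After length and GC correction Trim30a passed over all genes tested (limma adjusted p = 0.0463). Neither proliferation genes (18 genes, median 0.05, camera adjusted p = 0.591) nor survival and apoptosis genes (15 genes, median 0.012, mean -0.0019, positive camera direction, adjusted p = 0.962) held a call, over all genes tested or adjusted over the list alone. Both medians lacked a stable sign. That of proliferation was -0.021, -0.00064 and -0.075 without WT replicate 1, WT replicate 3 and KO replicate 1. That of survival was -0.00040, -0.022 and -0.072 without WT replicate 2, WT replicate 3 and KO replicate 4, and negative under TMM and median-of-ratios scaling. Mcm5, Ccnb2, Mcm3 and Mcm7 were at 0.88, 1.10, 0.47 and 0.39, and Birc3, Tnfrsf13c, Bcl2a1d and Bcl2 at 0.47, -0.49, -0.55 and 0.41.

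Across all 26 lists with at least 5 tested members, 11 passed camera, 7 lower and 4 higher in KO; 0 passed with an estimated correlation, and 6 passed under fry, 5 of them among the 11. After length and GC correction 6 passed (0 with an estimated correlation), 5 of them among the 11: the immunoglobulin constant, mitochondrially encoded, immediate early, MYC target and interferon lists.

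Markers of myeloid, T, NK and erythroid cells each summed to at most 0.0763% of the total of any library and did not move together. Among 10 tested myeloid markers Fcer1g fell from 36.6 ± 8.76 to 13.0 ± 5.13, a call that ended without WT replicate 2 or 3 or KO replicate 1 or 3 (limma adjusted p of up to 0.0906) and after length and GC correction (log2 fold change -1.48 to -1.25, SE 0.33 and 0.34; 0.0816). C1qc, C1qb and Tyrobp were at 1.95, 1.33 and 0.37 and did not pass. The myeloid list had 0 higher and 1 lower over all genes tested, 2 higher and 1 lower adjusted over the list alone, and did not pass (median -0.07, mean 0.11, negative camera direction, adjusted p = 0.962). Its median was 0.015, 0.064 and 0.33 without WT replicate 1, WT replicate 2 and KO replicate 1. Lists with fewer than 5 tested members were summed per library. T cell markers, of which Cd2 and Lck were tested (-0.20 and -0.79, not past the threshold), summed to 408 to 503 in WT and 334 to 409 in KO. NK cell markers summed to 7.86 to 28.6 in WT, 3.79 to 16.9 in KO replicates 1 to 3 and 104 in KO replicate 4, with Ccl5 at 8.5 in WT replicate 1, 0 in the other WT libraries, 66.8 in KO replicate 4 and 1.25 to 14.9 in the other KO libraries. Erythroid and platelet markers summed to 10.1 to 19.6 in WT replicates 2 to 4, 167 in WT replicate 1 and 31.0 to 35.6 in KO, with Hbb-bs at 58.8 in WT replicate 1, 3.14 to 6.46 in the other WT libraries and 7.73 to 10.6 in KO. Genes of pancreatic acinar cells, a list written after the call of Ctrb1 was seen, summed to 10.6 to 16.3 in WT, 28.6 to 37.1 in KO replicates 2 to 4 and 794 in KO replicate 1. Every KO library lay above every WT library, but Ctrb1, whose call prompted the list, adds to this gap. It made up 11.67 of the lowest KO sum, that of KO replicate 2, and at most 0.6976 of any WT sum. Only KO replicate 1 stood far above the rest. Without WT replicate 1 and KO replicate 1, 479 genes passed, 299 higher and 180 lower.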

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

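The tests of length trend, scaling and labels for the calls without WT replicate 1 were chosen only after the result was seen, as were the acinar gene list and the fits that leave out WT replicate 1 together with a correction or with KO replicate 1.

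In 322 groups of 4 values, for named genes and list sums, 22 had a library far from the other 3 by Dixon's ratio at its 95% critical value; chance gives about 1 in 20. WT replicate 1 accounted for 13 of the 22. Among list sums it held the highest WT value for B cell receptor signaling (22360, others 15280 to 16080), survival and apoptosis (1800, others 1258 to 1301), the integrated stress response (1294, others 1074 to 1110), T cell markers (502.9, others 407.7 to 420.4) and erythroid and platelet markers (167.2, others 10.13 to 19.58). Among genes it was the highest WT library for Bcl2 (140.0, others 66.22 to 76.97), Pdia4 (665.1, others 371.3 to 421.5), Tmc6 (98.36, others 64.00 to 68.35), Pgam1 (59.33, others 34.70 to 37.22), Hbb-bs (58.81, others 3.139 to 6.463) and Ccl5 (8.5, others all 0). It was the lowest WT library for Ndufa13 (601.8, others 749.2 to 779.0) and Rpl37a (7357, others 10110 to 10650).

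Leaving out WT replicate 1 multiplied the number of calls by 5.28, from 107 to 565. A trend over length and GC is not the whole account, since after its removal the calls still multiplied by 3.97, from 61 to 242, and neither is the scaling of the libraries, since under median-of-ratios scaling they multiplied by 3.61, from 173 to 624. A KO library under a WT label is argued against by Zfp318, which in WT replicate 1 was 33.9 times the highest KO value. The cause of its distance, which may be technical or a difference between the animals or cells sorted, stays open, and no biological explanation was tested because the labels set it apart in nothing.

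In KO replicate 1 pancreatic acinar genes summed to 794.0 (other KO libraries 28.59 to 37.06). NK cell markers summed to 103.7 in KO replicate 4 (other KO libraries 3.79 to 16.88). Single genes with a KO library apart were Irak1 in replicate 4 (106.4, others 90.33 to 92.84), Gpr183 in replicate 4 (140.9, others 126.9 to 128.9), Brwd1 in replicate 2 (183.6, others 155.5 to 156.0), Cox8a in replicate 2 (1092, others 831.1 to 874.8) and Ppp1r15a in replicate 3 (138.5, others 205.4 to 218.5). In WT, Ppp1r15a was highest in replicate 3 (193.1, others 126.5 to 135.1) and Cad in replicate 2 (53.82, others 34.66 to 37.30).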

How the results depend on the processing

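The length and GC correction, the fits leaving out WT replicate 1 together with another change or with KO replicate 1, camera with a variance trend, and an estimated correlation with any other change were chosen only after the result was seen. Zfp318 kept its direction and call in all 23 alternatives in which it was tested. Of 623 values of the 26 genes named by the first 2 parts of the rule, 507 stayed past the threshold in the same direction, 116 lost the call and 0 changed sign. The counts of changed, higher and lower genes moved most, for causes not tested beyond those the alternatives' construction shows. They were 24, 9 and 15 with no filter, 181, 86 and 95 with TMM, 173, 88 and 85 with median-of-ratios, and 176 and 102 (changed and higher) with quantile scaling. They were 16, 6 and 10 for limma without trend or robust, 479, 250 and 229 with array weights, 180, 93 and 87 with edgeR, 393, 184 and 209 with DESeq2, and 248, 112 and 136 at an adjusted p below 0.1. Leaving out a library gave 29 to 565 changed, 11 to 345 higher and 17 to 220 lower genes, the high end without WT replicate 1, and 29 to 62 changed without any other; fewer samples lower the power. Length and GC correction left 61 changed and 20 lower genes, or 242 and 189 (changed and higher) without WT replicate 1. Median-of-ratios without WT replicate 1 gave 624, 224 and 400, a share of higher genes below that of the 107, and leaving out WT and KO replicates 1 gave 479, 299 and 180.

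The replicate numbers gave no sign of pairing: same-numbered WT and KO libraries correlated at -0.086 to 0.015 in their deviations from group means, and 0 libraries correlated best with their own number. With the number as a block 93 genes changed, 51 higher and 42 lower, 84 of them among the 107, and 11 lists passed.

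Of the 26 lists, 11 passed camera; 6 did after length and GC correction, 6 after it without WT replicate 1, 6 under fry and 0 with an estimated correlation, alone or with the correction, without WT replicate 1, with both, or at a minimum mean of 50. Leaving out a library gave 8 to 14. Cytosolic ribosomal proteins turned from -0.06 to 0.14 with the correction (camera adjusted p = 1.8e-04, and 1.6e-10 with a variance trend, against 0.402 as reported and up to 0.998 over its 30 alternatives), but was at 0.11 (0.306) with the correction without WT replicate 1. Before the correction its median lay above those of all 10000 random lists matched on coding length and level (-0.24). Level was matched in only 4 bins, and the list held 28.6% to 38.3% of a library's total, so its match on level was loose. Removing the length and GC trends together turned it positive, and length alone was not tried. With a variance trend 11 lists passed, the same 11, and 9 after the correction, 8 of them among the 11, complex I (0.0224), antioxidant (0.0160) and plasma cell genes (0.0417) included. Depth limits genes under a mean of 10, which were not tested in the reported fit.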

Other observations

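The tests of IgG transcripts, of the light chains, of scaling and of the other splits of the libraries were chosen only after the result was seen; those of length-matched lists and of genes near Zfp318 were written before theirs.

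The receptor repertoire of the KO libraries differed in its variable segments. Iglv1, the lambda 1 segment typical of the response to NP in mice of the Igh-b allotype, fell from 3534 ± 563 to 1598 ± 100 (SD, n = 4; limma adjusted p = 1.3e-06), and its close copy Iglv2 fell from 1256 ± 148 to 585 ± 55.8. Ighv1-72, the heavy chain segment of that response, fell from 63.6 ± 23.5 to 22.2 ± 12.9 (adjusted p = 0.0116) and from 20.8% ± 2.98 to 8.48% ± 2.12 of heavy chain variable reads (exact permutation p = 0.0286, adjusted 0.0464). Lambda took 64.7% ± 1.51 of light chain constant reads in WT and 49.9% ± 0.860 in KO (exact permutation p = 0.0286, adjusted 0.0464). The lambda constant sum itself went from 10587 ± 1507 to 8754 ± 453 and did not pass (exact permutation p = 0.114, adjusted 0.135). Igkc rose from 5754.5 ± 499.7 to 8782 ± 364, so much of the lower share came from kappa. Summed lambda variable reads fell more, from 4963 ± 736 to 2312 ± 73.2 (exact permutation p = 0.0286, adjusted 0.0464). Of 64 tested kappa variable segments 45 had a positive log2 fold change, 8 were higher and 1, Igkv3-2, lower. Reads of similar segments could be split between copies, so the level of each is uncertain, and Ighv1-72 and Igkv3-2 lost their calls after length and GC correction (log2 fold changes -1.55 to -1.32, SE 0.31 and 0.34, adjusted p = 0.0691, and -2.20 to -1.95, SE 0.47 and 0.50, adjusted p = 0.0977).

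Several genes under the filter, chosen after their values were seen, were lower in KO without passing. Mcu, the pore of the mitochondrial calcium uniporter, had 135 reads over the WT libraries and 10 over the KO libraries, all in KO replicate 4 (6.03 ± 0.459 and 0.398 ± 0.795, n = 4; limma adjusted p = 0.0849 in the fit with no filter). Smdt1, which encodes another uniporter subunit, was past the filter and fell from 232 ± 31.3 to 155 ± 14.4 (adjusted p = 0.0479), a call kept in 1 leave-one-out fit of 8, that without WT replicate 1, and lost after length and GC correction (log2 fold change -0.57 to -0.46, SE 0.15 both times; 0.145). Tbx21, which encodes T-bet, stood at 10.3 ± 5.10 and 1.90 ± 1.45 (adjusted p = 0.204), and Itgax, which encodes CD11c, at 7.76 ± 2.45 and 0.948 ± 1.90 (adjusted p = 0.134). Ighe had 85 reads over the WT libraries and 0 over the KO libraries (adjusted p = 0.156). Scimp, an adaptor of Toll-like receptor and MHC class II signaling, was past the filter and fell from 51.4 ± 4.61 to 11.2 ± 4.99 (adjusted p = 1.2e-04) in all 8 leave-one-out fits too. Ctrb1, a pancreatic protease, was called higher in KO (adjusted p = 0.0085), at 134.4 in KO replicate 1, 6.251 to 13.36 in the other KO libraries, 0.6976 in WT replicate 3 and 0 in the other WT libraries; its call ended without KO replicate 1 (adjusted p = 0.128). In that library Cela2a stood at 152.9, Prss2 at 88.11 and Ctrl at 67.13.

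The lower level of nuclear mitochondrial genes in KO may follow in large part from the coding length trend. Among 10000 random lists matched on coding length and mean level, the median of complex I lay at percentile 6.62, that of complex IV at 25.2, ATP synthase at 82.5 and the mitochondrial ribosome at 66.6. For complex I the random lists had a median of -0.20 against -0.26, and the list passed camera after length and GC correction without WT replicate 1 (adjusted p = 0.0274) or with a variance trend (0.0224) but not otherwise (0.0626) nor with an estimated correlation (0.545 without WT replicate 1), so a part beyond the trend stays open. Complex I, complex IV and the mitochondrial ribosome kept their call under 3 rescalings, with a highest camera adjusted p of 7.1e-04, 0.0404 and 6.1e-04. The ATP synthase list did not (0.376). TMM and median-of-ratios move all genes of a library nearly alike, and camera compares a list with the other genes. Their outcome was thus nearly fixed in advance, and they decide nothing about scaling as a cause. Only quantile scaling could have ended these calls. The length trend and depth run along the groups, so whether the trend arose in library preparation or in the cells, through a loss of ZFP318, stays open and untested.

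The lower IgG transcripts in KO are not accounted for by length or by reads shared between the 4 IgG genes. After length and GC correction 4 of the 4 IgG genes still passed. Reads moving between the 4 genes could not lower all 4, and each was lower in every KO library than in any WT library. Their sum was lower by 1.73 on the log2 scale (log2 ratio -1.73, exact permutation p = 0.0286). Since each gene already separated the groups, the p of the sum was fixed in advance and adds nothing. A hypothesis is that the KO population held fewer switched cells and fewer cells with the lambda 1 receptor. If a single admixed population lacking both accounted for both falls, the log2 ratio of IgG to Iglv1 would not differ. The ratio was -2.08 ± 0.111 in WT and -2.68 ± 0.287 in KO (difference -0.60, exact permutation p = 0.0286). That argues against this simplest form, and a lower ratio decides nothing between cell numbers and transcript per cell. The summed kappa segments were higher by 0.38 without passing (exact permutation p = 0.0571). Fewer such cells and less transcript per cell cannot be told apart, since each library is a pool.

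Another hypothesis was that DNA of another strain flanking the Zfp318 allele could change genes near it. Within 10 Mb on chromosome 17, 2 of 59 tested genes were called, Pla2g7 and Tomm6, against 102 of 6738 elsewhere, an odds ratio of 2.28 (95% interval 0.266 to 8.84, Fisher's exact two-sided p = 0.228). The calls are too few to decide, and such DNA is not excluded for those genes.

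The 8 libraries can be split into 4 and 4 in 35 ways. The real split alone (1 of 35) gave as many as 107 changed genes, and the most in another split was 13, in one that put WT replicate 1 with 3 KO libraries. Likewise 1 of 35 gave as many as 54 higher or 53 lower genes, with 13 as the highest other in either direction. That is the smallest share that 35 splits allow. For the 3 counts the real grouping thus stood apart from the other splits of these libraries. A chance difference between pools or sorts is not excluded, since the labels do not say whether replicates are separate animals. For the lists, whether the real split stood alone depended on a setting chosen after both outcomes were seen. With camera's default 1 of 35 splits gave 11 lists or more and the highest other was 10, while with a variance trend 3 of 35 did and the highest other was 13, again with WT replicate 1 beside 3 KO libraries. Chance is therefore not excluded for the number of lists either.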
